A study of Homo sapiens with 4 samples.

How the data were processed

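DNA from 4 samples of purified human blood cells was bisulfite converted and sequenced from both ends on an Illumina instrument, per the labels' protocols and the series' design text. Bisulfite turns unmethylated cytosines into bases read as thymine and leaves methylated ones unchanged. From each sample the authors deposited 1 list of hypomethylated regions with a start, an end, a running number and a score per region. The genome build, hg18, was named with the deposited lists. The aligner and the region caller are not given in the sources used here. The lists hold no methylation level per CpG and no read counts, so depth was unknown and the precision that depth gives could not be stated.

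The meaning of the deposited score was not described by the labels. It was rarely a whole number (4.89% of CD133 HSC scores and 1.87% of HSPC scores), so it was not a CpG count. Divided by the largest number of CpGs that a region of its width can hold, the highest score was exactly 1 in each list. A score counted as a multiple of 1/12 when 12 times the score lay within 0.00024 of a whole number. It was therefore read, as an inference from the values, as a sum of unmethylated fractions over the CpGs of a region, and it was used to describe and filter regions. Region numbers ran on through the HSPC, neutrophil and B cell lists, while the CD133 HSC list was numbered separately. Its lowest score was also lower than that of the other 3, so its comparisons are confounded with that calling run. The authors' threshold and filters can set which weak regions appear in a list: a region missing from a list may have been just short of its threshold.

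Only autosomes 1 to 22 were used, and X and Y were not analysed here. This kept 47971 of 49593 CD133 HSC regions, 53535 of 55984 HSPC regions, 51156 of 53834 B cell regions and 58365 of 60594 neutrophil regions. Samples were grouped by the cell type in their labels, with 1 sample per group, and the labels do not say whether samples shared a donor. Positions are counted from 1.

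Regions of separate lists were called overlapping when they shared at least 1 bp. Overlapping or touching regions of the 4 lists were merged into loci, and each locus was given 1 of 15 presence patterns. Gained regions were those of a mature list without overlap in a progenitor list, and lost regions the reverse. Widths were compared over 1-to-1 regions, in which each region overlapped exactly 1 region of the other list. A region more than 200 bp wider counted as extended on 1 side when at least 90% of the added length was there. Only length beyond the narrower region was added up. A region whose other end lay inside the narrower one therefore also counted as extended on 1 side. Shares were given exact (Clopper-Pearson) 95% binomial intervals. These treat regions as independent and cover counting error only. Overlap and nearness to loci in all 4 lists were set beside 100 seeded circular shifts within each autosome, and clustering beside 100 seeded draws from the same list. With 1 sample per group there was no test between groups.

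Named regions followed a rule fixed before the data were examined. For each exclusive pattern, for HSPC with neutrophils, HSPC with B cells and both mature cell types, the 5 widest loci were named. For each progenitor and mature pair, the 3 largest width gains and losses were named, and for each list the 2 windows of 1 Mb with the most exclusive regions. Width took the place of the planned CpG count, because the score was not one. Counts of promoter regions for fixed gene lists were planned for an hg18 annotation. The gene table at hand was for GRCh38.p14, and positions were not converted between builds, so those counts were not run and no gene is named.

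Alternatives fixed before the data were examined were an overlap of at least 50% of the shorter region, regions of at least 500 bp, equal lists of the widest 47971 regions, joining of regions of a list under 500 bp apart, distances of 5 kb and 20 kb in place of 10 kb, and a width difference over 500 bp. Chosen after the data were seen were 1 lowest score for the 4 lists, scores of at least 20, scores of at least 20 set against all regions of the other list, and leaving out the CD133 HSC list. The functions were checked on simulated lists with 42828 regions in the first of them, 32121 shared regions and 200 regions extended on 1 side. All 8 simulated quantities were recovered exactly. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.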

Results

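Hypomethylated regions, the short stretches of low CpG methylation that interrupt the mostly methylated human genome, were compared between blood cells at different stages of maturation. Each of 4 samples contributed 1 region list from bisulfite sequencing. HSPC (hematopoietic stem and progenitor cells) and CD133 HSC (stem cells carrying the surface marker CD133, from umbilical cord blood) were the progenitor samples. B cells, the lymphocytes that make antibodies, and neutrophils, the most abundant granulocytes of blood, were the mature samples. Each group held 1 sample, so no value has a replicate error and no p-value is given. Intervals are exact 95% binomial intervals for counting error only, and ranges over the 22 autosomes describe spread within a genome. Read depth was unknown, because the lists hold no read counts.

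The neutrophil list was the longest and the CD133 HSC list the shortest. On the autosomes the neutrophil list held 58365 regions covering 58.9 Mb, HSPC 53535 regions covering 55.0 Mb, B cells 51156 regions covering 53.7 Mb and CD133 HSC 47971 regions covering 48.3 Mb. Median widths were similar, at 701 bp in B cells, 676 bp in HSPC, 668 bp in neutrophils and 617 bp in CD133 HSC. Very long regions were rare in B cells, which had 8 regions of 20 kb or more, against 36 in CD133 HSC, 31 in HSPC and 30 in neutrophils. After regions of a list under 500 bp apart were joined, the numbers were 31 in B cells, 44 in CD133 HSC, 38 in HSPC and 38 in neutrophils. The CD133 HSC list was numbered separately from the other 3 and had a lower lowest score, so its contrasts with the others coincide with a separate calling run.

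**Figure D1:**
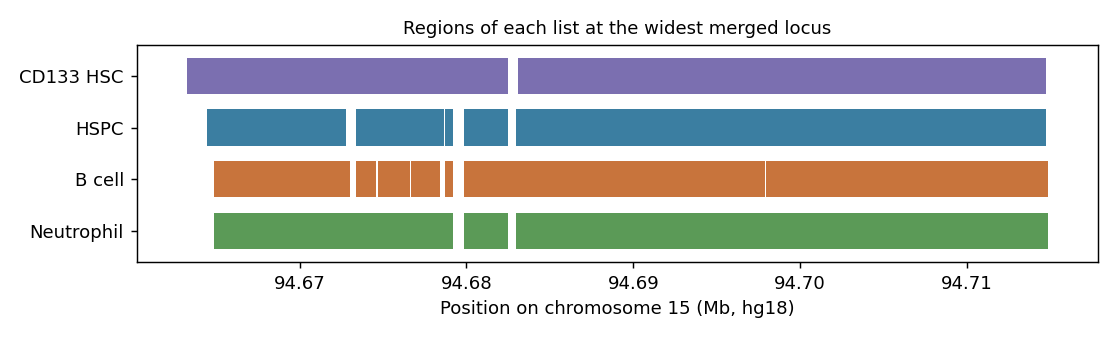
Regions of each list (rows) along the widest merged locus, on chromosome 15 at 94663229 to 94714879; the horizontal axis is the hg18 position in Mb. The bars are single regions, 7 in B cells, 5 in HSPC, 3 in neutrophils and 2 in CD133 HSC.

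The study's title asks how methylation changes with lineage, and pairwise overlap gave a first answer on which cell types resembled each other. HSPC and neutrophils were the most alike pair, and B cells and neutrophils the least alike. Neutrophil regions overlapped 93.0% of HSPC regions (interval 92.8 to 93.2), whereas B cell regions overlapped 76.8% of them (76.4 to 77.1). Measured in bases, the Jaccard index (shared bases over all bases covered by either list) was 81.5% for HSPC with neutrophils and 75.03% for the progenitor pair. It was 70.8% for CD133 HSC with B cells, 70.7% for CD133 HSC with neutrophils, 69.4% for HSPC with B cells and 65.3% for B cells with neutrophils. Circular shifts of the HSPC list within each autosome left 4.73% of its regions overlapped by neutrophils on average (range 4.31 to 5.09 over 100 shifts). Overlap rose with the deposited score: over 4 equal score classes, neutrophils overlapped 78.8% of HSPC regions in the lowest class and 100.0% in the highest, and B cells 44.9% and 99.98%.

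Most of the hypomethylated bases were common to all 4 cell types, and loci held by 1 list were narrower and mostly of low score. Of 72.6 Mb covered by any list, 40.4 Mb (55.6%) lay in every list and 16.9 Mb (23.3%) in 1 list only. Merging the lists gave 71718 loci, of which 36584 (51.0%, interval 50.6 to 51.4) occurred in every list and 18894 (26.3%, 26.0 to 26.7) in 1 list only. Loci in all 4 lists had a median width of 1102 bp, against 257 to 461 bp for loci in 1 list. Merging widens the former: the single regions at loci in all 4 lists had median widths of 812 bp (CD133 HSC) to 934 bp (neutrophils). B cells had 7191 loci found nowhere else and neutrophils 6793, against 3095 in CD133 HSC and 1815 in HSPC. This order depended on list length and score limit. Equal lists of the widest regions gave 6752 exclusive regions in B cells, 4509 in neutrophils, 5067 in CD133 HSC and 1751 in HSPC. With 1 lowest score for the lists the counts were 7439, 7028, 1848 and 1935. Among loci in exactly 2 lists, the pair of HSPC and neutrophils stood out with 6190, while no other pair exceeded 831. Loci shared by the mature cell types alone numbered 594 and those shared by the progenitor samples alone 620. Of the B cell-exclusive regions, 76.2% had a score under 10, as had 92.1% of those of neutrophils, 94.0% of HSPC and 92.9% of CD133 HSC. Among regions at loci in all 4 lists these shares were between 20.99% and 26.5%.

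**Figure D2:**
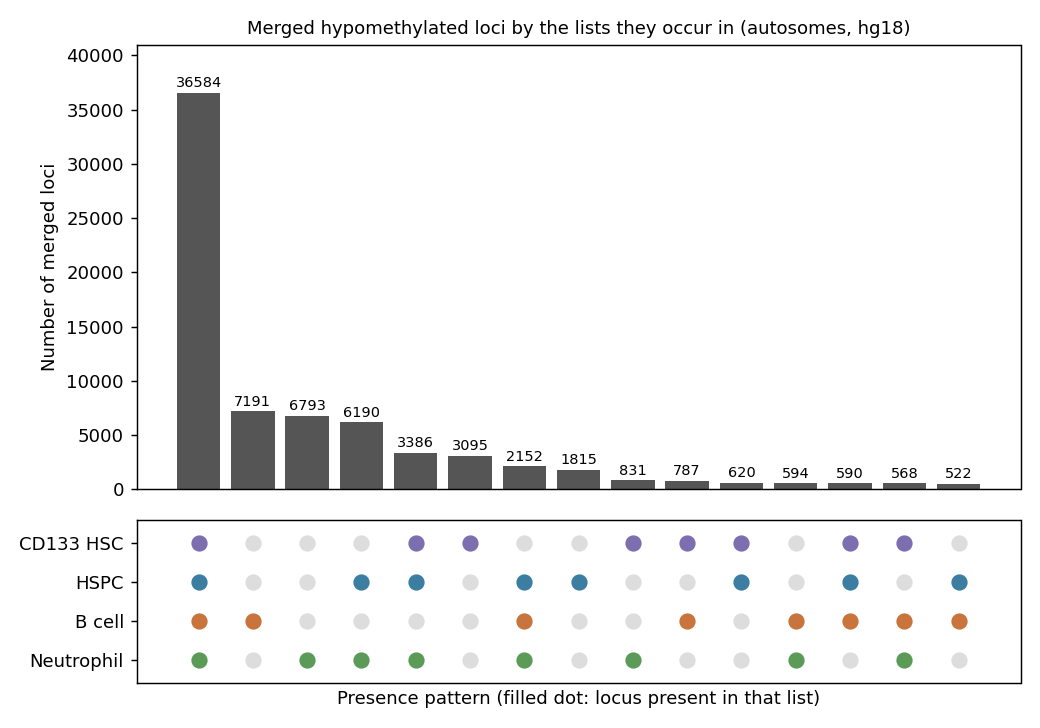
Number of merged autosomal loci (vertical axis) for each of the 15 combinations of lists (columns, with filled dots marking the lists that hold the locus). Loci in all 4 lists number 36584, and HSPC with neutrophils is the only pair with a count, 6190, near those of B cells alone (7191) and neutrophils alone (6793).

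Progenitor loci that were kept in only 1 mature cell type were mostly shared with neutrophils. HSPC shared 9576 loci with neutrophils but not B cells, and 1112 with B cells but not neutrophils, so 89.6% of these loci were on the neutrophil side (interval 89.0 to 90.2, autosomes 85.7 to 93.8). For CD133 HSC the counts were 4217 and 1377, and the neutrophil share was 75.4% (74.2 to 76.5, autosomes 68.0 to 85.6). The CD133 HSC imbalance lay in loci that HSPC also had: at loci absent from HSPC, CD133 HSC shared 831 with neutrophils and 787 with B cells, a neutrophil share of 51.4% (48.9 to 53.8). Among HSPC regions with a score of at least 20, 222 overlapped neutrophils but not B cells and 17 overlapped B cells but not neutrophils (92.9%, 88.9 to 95.8). For CD133 HSC these counts were 111 and 9 (92.5%, 86.2 to 96.5). With the lists trimmed to equal numbers of their widest regions, the neutrophil share fell to 71.0% for HSPC and to 44.2%, below an even split, for CD133 HSC. Trimming took the neutrophil list from 58365 and the B cell list from 51156 to 47971 regions, and left the CD133 HSC list whole. This unequal cut can itself lower the neutrophil share.

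The widest loci held by HSPC and neutrophils alone were each wider in neutrophils. On chromosome 11, positions 59579789 to 59583345 (hg18, as are all positions here), the region was 2490 bp wide in HSPC and 3557 bp in neutrophils, with scores of 21.7 and 38.0. On chromosome 14, positions 21965714 to 21969156, it was 2812 bp in HSPC and 3443 bp in neutrophils, with scores of 25.7 and 31.4. The other 3 of the widest 5 lay on chromosome 13 (40444487 to 40448133 and 109239016 to 109242529) and chromosome 6 (25273561 to 25277031). The widest loci of HSPC and B cells alone lay on chromosome 5, at 99410246 to 99413541 (2655 bp in HSPC, in 2 regions, and 3296 bp in B cells) and at 133296164 to 133299257 (412 bp and 3094 bp). The remaining 3 lay on chromosomes 2, 17 and 3, with starts at 194404107, 21921535 and 103137968. For the mature cell types alone, the widest was on chromosome 14, positions 19628841 to 19632960, at 4120 bp in B cells and 1667 bp in neutrophils. The next 4, on chromosomes 2, 6, 11 and 17 (starts 87577211, 33103614, 72540683 and 22298759), were also wider in B cells. The genes at these positions were not looked up, since no annotation of hg18 was used here.

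Maturation was described next by regions present in a mature list and absent from a progenitor list (gained) or the reverse (lost). Relative to HSPC, neutrophils gained more regions than they lost, and B cells lost more than they gained. Neutrophils had 8911 gained and 3741 lost regions, a gained share of 70.4% (interval 69.6 to 71.2), with all 22 autosomes above an even split (66.3 to 73.5). B cells had 9256 gained and 12440 lost regions, a gained share of 42.7% (42.0 to 43.3), with 0 of 22 autosomes above an even split (38.9 to 49.1). Relative to CD133 HSC, both mature cell types gained more than they lost, at 16025 against 5227 in neutrophils (75.4%, 74.8 to 76.0) and 10668 against 8225 in B cells (56.5%, 55.8 to 57.2). An excess of this kind was also present between the progenitor samples: relative to CD133 HSC, HSPC had 11111 gained and 5393 lost regions (67.3%, 66.6 to 68.0).

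These asymmetries against HSPC lay mostly in regions of low score, and at high score they depended on how overlap was counted. The median score of gained regions was 7.28 in B cells and 6.51 in neutrophils. Among regions with a score of at least 20, set against all regions of the other list, B cells had 255 gained and 229 lost relative to HSPC (52.7% gained, interval 48.1 to 57.2). Neutrophils had 28 gained and 24 lost (53.8%, 39.5 to 67.8, on 52 regions). Both intervals held an even split, so neither direction was detectable in this comparison. When the score limit was applied to both lists, a weaker region no longer counted as an overlap. The gained shares were then 41.2% in B cells (39.2 to 43.1) and 67.0% in neutrophils (64.4 to 69.4), so both directions were kept. Against CD133 HSC the gained excess was larger at this score, with 338 gained and 147 lost in B cells (69.7%, 65.4 to 73.8) and 335 and 45 in neutrophils (88.2%, 84.5 to 91.2). HSPC had 181 gained and 53 lost against CD133 HSC (77.4%, 71.4 to 82.5). With equal numbers of the widest regions per list the gained share is held near an even split by construction, and for B cells against CD133 HSC it was 49.2%. Over all regions, gained minus lost had the sign of the difference in list length. It was 5170 from HSPC to neutrophils for a list 4830 regions longer, and -3184 from HSPC to B cells for a difference of -2379. From CD133 HSC it was 10798 for a difference of 10394 in neutrophils and 2443 for a difference of 3185 in B cells.

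Shared regions also differed in width, and here too B cells and neutrophils departed from HSPC in opposite directions. Among 1-to-1 regions of unequal width, 57.4% were wider in neutrophils than in HSPC (interval 56.9 to 58.0, autosomes 53.9 to 64.4) and 43.1% were wider in B cells than in HSPC (42.5 to 43.7, autosomes 38.8 to 46.6). Relative to CD133 HSC, 68.7% were wider in neutrophils (68.1 to 69.2) and 58.8% in B cells (58.3 to 59.4), and so were 66.9% in HSPC (66.4 to 67.5). The median showed little net direction. The median log2 width ratio was 0 for neutrophils and B cells over HSPC and for B cells over CD133 HSC. It was 0.02 for neutrophils over CD133 HSC. Regions of equal width hold this median near 0. Where widths were unequal, the median difference was 97 bp between HSPC and neutrophils and 131 bp between HSPC and B cells. Both ends were identical in 35.9% of the 47312 region pairs of HSPC and neutrophils, and in 24.96% of the 38198 pairs of HSPC and B cells.

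In shared regions of unequal width the wider region mostly contained the narrower one, whichever list was wider. Where the width difference was large, the added length mostly lay beyond 1 end of the narrower region. The wider region contained the HSPC region in 87.4% of 17390 neutrophil regions (interval 86.9 to 87.9) and 80.9% of 12353 B cell regions (80.2 to 81.6). Where HSPC was wider, its region contained the neutrophil region in 84.5% of 12894 (83.9 to 85.1) and the B cell region in 86.1% of 16295 (85.6 to 86.7). A shared end makes containment certain. Of the 47312 HSPC and neutrophil pairs, 45.5% had exactly 1 identical end, as had 46.1% of the 38198 HSPC and B cell pairs. Such pairs are all of unequal width, so their share is higher among the 30284 and 28648 pairs of unequal width. Containment thus mostly restates shared ends. Among regions more than 200 bp wider in the mature cells than in HSPC, at least 90% of the added length lay on 1 side in 73.8% of 4689 neutrophil regions (interval 72.5 to 75.04) and 71.1% of 4357 B cell regions (69.8 to 72.5). Among regions more than 200 bp wider in HSPC, the added length lay on 1 side in 78.9% of 2743 regions against neutrophils (77.4 to 80.4) and 62.6% of 5496 against B cells (61.4 to 63.9). These shares include pairs whose other end lay inside the narrower region, so the other end need not be unchanged. A pair with 1 identical end also counts as extended on 1 side by definition. How many of these regions had an identical end was not counted, so the shares may largely restate shared ends. Relative to CD133 HSC the one-sided shares were 60.0% of 8217 neutrophil regions (59.0 to 61.1) and 62.6% of 6418 B cell regions (61.4 to 63.7). Where CD133 HSC was wider they were 67.9% of 2355 against neutrophils and 61.8% of 3430 against B cells.

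**Figure D3:**
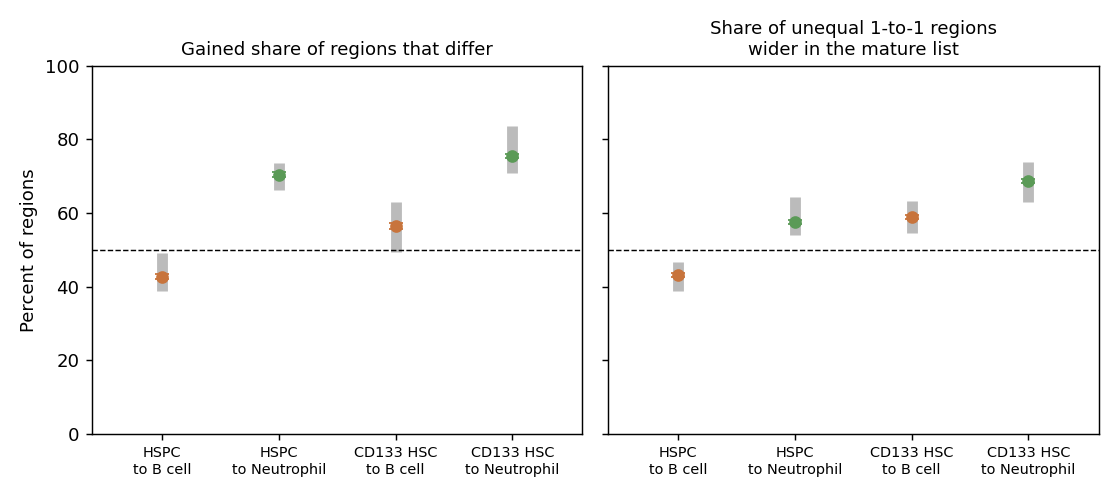
Percent of regions (vertical axis, 0 to 100) that were gained among regions that differ (left panel) and that were wider in the mature list among unequal 1-to-1 regions (right panel), for each progenitor to mature pair. Points are values over the 22 autosomes, thin bars the exact 95% binomial intervals, grey bars the range over single autosomes and the dashed line an even split at 50%; B cells against HSPC lie below it in both panels (42.7% and 43.1%).

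The largest B cell gain in width over HSPC was on chromosome 14, where a region of 4603 bp (105398367 to 105402969) extended to 9735 bp (105393033 to 105402767). A region on chromosome 18 grew from 1954 bp to 6947 bp (51134821 to 51141767 in B cells), and one on chromosome 11 from 1309 bp to 6170 bp (101692614 to 101698783), with its start unchanged. The chromosome 18 and 11 regions were also among the 3 largest B cell gains over CD133 HSC, where they measured 1816 bp and 889 bp; the other, on chromosome 3, was 2154 bp in CD133 HSC and 7031 bp in B cells (16526507 to 16533537). The largest B cell losses against HSPC were on chromosome 6 (8676 bp to 4096 bp, 82512763 to 82521438 in HSPC), chromosome 10 (5768 bp to 1396 bp, 73200751 to 73206518) and chromosome 12 (5555 bp to 1994 bp, 52976923 to 52982477). The same chromosome 6 position was among the 3 largest neutrophil gains over CD133 HSC, from 4203 bp to 8973 bp. The largest of those was on chromosome 17, from 244 bp to 7237 bp (53707458 to 53714694), and the next on chromosome 11, from 1477 bp to 6962 bp (93916159 to 93923120).

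The named width gains of neutrophils over HSPC were smaller than those of the other pairs. Their losses were not all smaller: the largest (-3286 bp) exceeded the largest neutrophil loss against CD133 HSC (-2799 bp). The largest gain was on chromosome 16, from 284 bp to 3373 bp (88806341 to 88809713 in neutrophils), followed by 2 on chromosome 6, of 2569 bp (109804633 to 109811583) and 2443 bp (124165215 to 124171576). The largest losses were on chromosome 10 (4338 bp to 1052 bp), chromosome 2 (5478 bp to 2940 bp) and chromosome 8 (2969 bp to 622 bp). The chromosome 2 region, at 113749619 to 113752558 in neutrophils, was also the largest loss against CD133 HSC, where it measured 5739 bp. The next losses against CD133 HSC were on chromosome 2 (2927 bp to 496 bp, 232958633 to 232961559 in CD133 HSC) and chromosome 5 (2811 bp to 435 bp, 140190050 to 140192860). B cells lost most against CD133 HSC on chromosome 5 (4388 bp to 1066 bp, 140726187 to 140730574), chromosome 6 (6951 bp to 4382 bp) and chromosome 17 (5903 bp to 3401 bp, 52687743 to 52693645).

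Regions exclusive to 1 cell type were examined for size, strength and position. B cells had the most high-scoring exclusive regions: 200 of the 231 with a score of at least 20 over the 4 lists (86.6%), against 20 in CD133 HSC, 8 in neutrophils and 3 in HSPC. Neutrophil regions shared only with HSPC do not count as exclusive, and 213 of those had such a score. Between the mature lists alone, 423 neutrophil regions of this score lacked a B cell overlap, against 263 B cell regions that lacked a neutrophil overlap. The widest B cell-exclusive region, on chromosome 10 at 98016722 to 98024086, was 7365 bp wide with a score of 48.6. It was followed by chromosome 20 at 42643196 to 42650067 (6872 bp, score 44.2), chromosome 2 at 88913254 to 88919370 (6117 bp, score 23.5), chromosome 11 at 59978748 to 59983119 (4372 bp, score 24.2) and chromosome 2 at 230775342 to 230779689 (4348 bp, score 29.7). No exclusive region of neutrophils or CD133 HSC was as wide: their widest were 3008 bp on chromosome 8 (43831237 to 43834244, score 6.58) and 3257 bp on chromosome 9 (69084608 to 69087864, score 6.83). The widest HSPC-exclusive region was 4070 bp on chromosome 3 (75871919 to 75875988, score 12.9). The next 4 neutrophil-exclusive regions were on chromosomes 1, 14, 17 and 12 (starts 116323974, 57569455, 29644170 and 95418719). Those of HSPC were on chromosomes 10, 21, 16 and 9 (starts 39082922, 13458176, 32428559 and 67259670), and those of CD133 HSC on chromosomes 10, 19, 21 and 7 (starts 54230255, 15722611, 13694442 and 61166214). Per 100 bp, the score was 0.38 to 0.68 for the 5 B cell regions and 0.20 to 0.42 for the 15 of the other lists. Over all exclusive regions the order was different: the median score per 100 bp was 1.82 in B cells, 1.80 in neutrophils, 2.41 in HSPC and 2.51 in CD133 HSC. The nearest locus in all 4 lists lay 713 to 30543 bp from the 5 named B cell regions. For the 15 named regions of the other lists this distance ranged from 2405 to 983558 bp. Whether reads map uniquely at the named positions cannot be read from region lists.

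Exclusive regions lay near loci hypomethylated in every cell type more often than shifted positions did. Within 10 kb of such a locus were 49.4% of the B cell-exclusive regions (interval 48.2 to 50.5), 45.2% of those of neutrophils (44.0 to 46.4), 43.6% of HSPC (41.3 to 45.9) and 42.6% of CD133 HSC (40.9 to 44.4). Circular shifts gave means of 24.3%, 23.3%, 23.4% and 23.2%, and no single shift exceeded 28.3%. The shifts ignored gaps in the assembly, so they describe these lists and are no test.

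Exclusive regions of B cells were clustered along the genome. Of these, 28.6% had another B cell-exclusive region within 10 kb, whereas draws of as many regions from the whole B cell list gave 15.2% on average and at most 17.1%. In neutrophils the share was 18.4% (draws 13.9%, at most 14.9%), in CD133 HSC 8.56% (6.67%, at most 8.37%) and in HSPC 6.01%, which equalled the highest draw. Clustering was computed with the main settings only, so pieces of a stretch split by short gaps can count as neighbours here. The 1-Mb window with the most B cell-exclusive regions lay on chromosome 14, at 105000001 to 106000000, and held 44 of them, against 4 exclusive to neutrophils, 3 to CD133 HSC and 0 to HSPC; it also contained the largest width gain of B cells over HSPC. The next B cell window, on chromosome 19 at 2000001 to 3000000, held 30. CD133 HSC had its densest window on chromosome 5, at 140000001 to 141000000, with 32 exclusive regions and 209 regions in all, against 176 in HSPC, 167 in neutrophils and 130 in B cells. Its next window, on chromosome 9 from 137000001, held 11. The top neutrophil windows, on chromosome 7 from 2000001 and chromosome 17 from 76000001, held 18 and 17 neutrophil-exclusive regions but also 22 and 19 exclusive to B cells. The top HSPC windows, on chromosome 16 from 1000001 and chromosome 1 from 3000001, held 11 and 7 HSPC-exclusive regions but 12 and 12 exclusive to B cells.

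**Figure D4:**
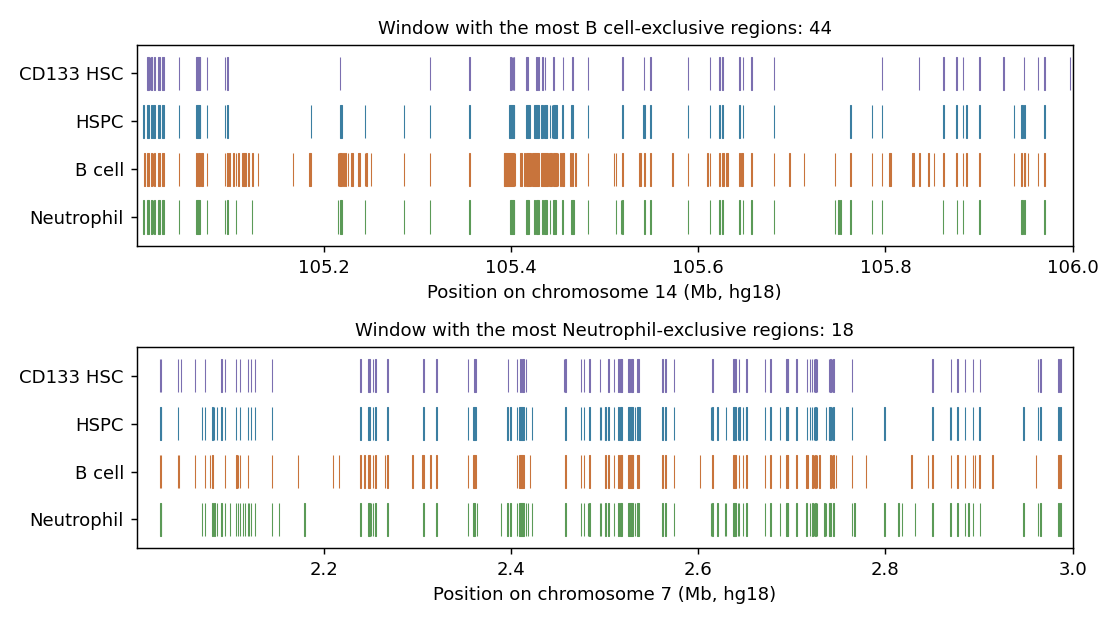
Regions of each list (rows, colored bars) along the 1-Mb windows with the most B cell-exclusive regions (top, chromosome 14, 44 exclusive regions) and the most neutrophil-exclusive regions (bottom, chromosome 7, 18 exclusive regions); the horizontal axis is the hg18 position in Mb. On chromosome 14 the B cell row holds 107 regions against 57 to 64 in the other rows, and on chromosome 7 the neutrophil row holds 107 against 77 to 93.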

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

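Of the tests in this part, those of the lowest score, of scores of at least 20 or under 20 and of read depth were chosen after the result they measure was seen. B cells and neutrophils moved in opposite directions relative to HSPC: the gained share was 42.7% for B cells and 70.4% for neutrophils, and the share of unequal regions that were wider was 43.1% for B cells and 57.4% for neutrophils. B cells also stood on opposite sides of an even split depending on the progenitor sample, with a gained share of 56.5% and a wider share of 58.8% against CD133 HSC. These differences were not tested, because each group held 1 sample. Gained shares depend on list length. For scores of at least 20 set against all regions of the other list they were 52.7% for B cells and 53.8% for neutrophils against HSPC, and 69.7% for B cells against CD133 HSC. With equal lists, the wider shares against HSPC were 42.1% for B cells and 59.1% for neutrophils.

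The preference of HSPC for neutrophil loci was weighed against technical explanations. If it came from the longer neutrophil list alone, it should vanish at equal list lengths, but the neutrophil share was then still 71.0% (interval 70.2 to 71.9), down from 89.6%. If the HSPC library held a minor share of neutrophil-like DNA, HSPC scores at loci of this pair should be well below those of neutrophils, relative to loci in all 4 lists. The quotient of the median score ratios was 0.945 for regions with identical ends, above the bound of 0.9 set beforehand, but that bound took no account of selection: only regions called in HSPC enter, and 44.3% of neutrophil loci outside the B cell list had no HSPC region, so a minor share stays open. A biological explanation, a myeloid-leaning methylation state in most cells of the progenitor sample, also stays open, as an untested hypothesis, as do donor differences.

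A single widening factor for all regions of a list was tested as an explanation of the width differences. A large factor would move the median. The largest distance of the median log2 width ratio from 0 over the 4 pairs was 0.017, which leaves out a large common factor, while the wider shares ranged from 43.1% to 68.7%. Widths were equal in 22.5% to 36.0% of 1-to-1 regions, depending on the pair, which holds the median at or near 0. A small shift common to a list can thus not be excluded, and whether lineage or calling sets the width differences stays open.

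The CD133 HSC list held 0.896 times as many regions as the HSPC list. Its lowest score minus that of HSPC was -0.556, and a lower limit can only lengthen a list, so the score limit does not account for the shortage; raising it to the common limit could only lower the ratio, which became 0.833. Loss of weak regions was tested by the share of the highest of 4 equal HSPC score classes with a CD133 HSC overlap, 99.99%, but the same share was 99.966% or more for every other pair of lists, so the measure was saturated; the ratio was 0.955 at scores of at least 20 and 0.856 below 20 (0.7495 below 20 with 1 lowest score). Lower read depth may play a part, since 18.5% of low CD133 HSC scores were multiples of 1/12 against 6.27% in HSPC, but neutrophils had 12.8% and the longest list. Depth, calling run and cell source cannot be told apart here, because the CD133 HSC sample differs from the rest in all of them or their values are unknown.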

How the results depend on the processing

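Settings that used the score or left out the CD133 HSC list were chosen after the data were seen. No paired analysis was possible because each group held 1 sample and the results come from no test. Each of 16 main results was bounded by the interval of its main value, or by 1.5 times for counts. An overlap of at least 50% of the shorter region moved none beyond its bound. Leaving out CD133 HSC moved none of the 3 results it could be run on, but says little about their stability. The counts of loci in all lists and in 1 list then cover only the remaining lists. The neutrophil share of HSPC loci ignores CD133 HSC by definition, so it could change only through the merging of loci. Over all settings, 46 alternative values of the 16 main results stayed within their bounds, 64 moved and 3 changed direction, that is, crossed an even split. Direction was defined for gained, wider and neutrophil shares only, not for shares of exclusive regions near a locus, which passed 50% at 20 kb. For the other 32 results, 81 alternative values stayed and 91 moved. Staying meant within 0.5 percentage points for a Jaccard index and within 0.1 for a median log2 width ratio. Some of these could hardly move. The Jaccard index does not use the overlap rule, so an overlap of at least 50% left it unchanged by construction. Equal widths hold the median log2 width ratios near 0. With a width difference over 500 bp, one-sided shares were 64.0% for B cells and 72.7% for neutrophils over HSPC, and 55.9% and 53.6% over CD133 HSC. Depth was unknown, so how far it limits weak regions was not tested; for values that moved or changed direction, the cause was not tested unless stated.

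The 3 changes of direction were the neutrophil share of CD133 HSC loci, 44.2% in equal lists, the gained share from CD133 HSC to B cells, 49.2% in equal lists, and that from HSPC to B cells, 52.7% for scores of at least 20 against all regions. Equal lists push gained and lost counts together by construction, and the other gained shares were 48.6% (HSPC to B cells), 51.3% (HSPC to neutrophils) and 51.5% (CD133 HSC to neutrophils). Equal lists also cut more neutrophil than B cell regions and no CD133 HSC regions, which can itself lower a neutrophil share. The neutrophil share of HSPC loci was 71.0% in equal lists. Wider shares in equal lists were 42.1% and 59.1% for B cells and neutrophils over HSPC, and 59.5% and 70.9% over CD133 HSC. Exclusive regions near a locus in all 4 lists made up 45.5% in B cells and 39.4% in neutrophils.

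With regions of at least 500 bp, 23096 loci were in all 4 lists and 11154 in 1, since fewer regions entered. The neutrophil share of HSPC loci was 87.5%. Gained shares were 45.2% and 69.2% for B cells and neutrophils from HSPC, and 70.1% and 84.1% from CD133 HSC. Wider shares over CD133 HSC were 56.5% and 66.9%. Exclusive regions near a locus in all 4 lists were 34.1% in B cells, 30.8% in HSPC, 32.0% in neutrophils and 29.5% in CD133 HSC. Joining regions under 500 bp apart gave 46.4%, 38.7%, 42.4% and 38.7% in that order, a gained share of 71.4% from HSPC to neutrophils and a wider share of 58.1% in B cells over CD133 HSC. At 5 kb the shares near such loci were 34.0%, 30.5%, 30.2% and 28.9%, and at 20 kb 65.6%, 59.3%, 62.8% and 57.3%, as a shorter or longer distance must give.

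With a score of at least 20 in every list, 19355 loci were in all 4 lists and 1941 in 1, again with fewer regions. Neutrophil shares were 88.5% for HSPC and 85.9% for CD133 HSC. Gained shares were 41.2% and 67.0% for B cells and neutrophils from HSPC, and 59.2% and 80.4% from CD133 HSC. Wider shares were 41.9% and 54.9% over HSPC, and 54.0% and 63.3% over CD133 HSC. Exclusive regions near a locus in all 4 lists were 37.6% in B cells, 27.3% in HSPC, 34.4% in neutrophils and 36.1% in CD133 HSC. Scores of at least 20 against all regions gave neutrophil shares of 92.9% for HSPC and 92.5% for CD133 HSC, and gained shares of 53.8% from HSPC to neutrophils, 69.7% from CD133 HSC to B cells and 88.2% from CD133 HSC to neutrophils. With 1 lowest score, the results with CD133 HSC moved: its neutrophil share was 77.3%, gained shares were 66.1% for B cells and 83.5% for neutrophils, wider shares 57.6% and 67.5%, and its exclusive regions near a locus in all 4 lists 45.1%.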

Other observations

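The longest hypomethylated stretches were shared by all 4 cell types but were broken into more pieces in B cells. The 42 merged loci of 20 kb or more held 163 B cell regions, against 73 in HSPC, 71 in neutrophils and 56 in CD133 HSC. Loci that held exactly 1 region of a list numbered 5 in B cells, 22 in HSPC, 23 in neutrophils and 30 in CD133 HSC. The covered share of a locus was nevertheless high in B cells, with a median of 96.0%, against 98.4% in HSPC. The widest locus lay on chromosome 15 at 94663229 to 94714879 and held 7 B cell, 5 HSPC, 3 neutrophil and 2 CD133 HSC regions. On chromosome 2 at 176639352 to 176689971, HSPC and CD133 HSC had 1 region of 50509 bp and 50438 bp, while neutrophils had 4 regions and B cells 8, the widest of 14890 bp. On chromosome 12 at 52606190 to 52651349 there were 1 CD133 HSC, 4 HSPC, 3 neutrophil and 8 B cell regions. These loci were chosen after their values were seen.

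The shortage of B cell regions of 20 kb or more may come from short gaps that split long regions. When regions under 500 bp apart were joined, the B cell number rose from 8 to 31 and that of HSPC from 31 to 38, so B cells reached 81.6% of the HSPC number, above the 80% set as the bound before the result was seen. Whether the gaps hold methylated CpGs or thinly covered ones cannot be read from region lists.

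At loci with 1 region in each of the 4 lists, the HSPC width was closer to the neutrophil than to the B cell width in 63.6% of the loci where those differed (interval 63.0 to 64.2). For CD133 HSC this share was 51.7% (51.1 to 52.3). The HSPC width lay strictly between the mature widths at 26.6% of these 25243 loci, and outside them at 32.7%.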
